A study of Macaca mulatta and Rattus norvegicus and Mus musculus with 33 samples.

How the data were processed

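Bulk ATAC-seq libraries of macaque, rat and mouse tissues were analysed from 57 deposited peak files, namely a per-library list for each of the 33 libraries and copies of 15 sets of reproducible peaks, each for 1 tissue of 1 species. No such set for macaque muscle or dorsal S1 was used here. The submitters' processing notes name MACS2 as a tool for all 3 species, Bowtie2 for macaque only, and the builds Mmul_8.0.1 (macaque), rn6 (rat) and mm10 (mouse). Versions, and the aligner for rat and mouse, are not given in the sources used here. The names of the deposited lists carry marks for duplicate removal, a shift of reads for the transposase, a limit on the number of peaks and a blacklist filter, and no label states these steps. Peaks were called per library in the lists; which libraries went into each reproducible set is not given in the sources used here.

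Each deposited peak carries a −log10 p-value and a −log10 q-value, both the authors' own values from their caller, which grow with sequencing depth. The deposited lists also give a fold ratio of each peak over its local background, again the authors' value. Values of single peaks were used only to order or filter peaks within 1 list. The deposited files hold no read counts, so depth per library is unknown, and fewer or weaker reads show only as weaker intervals at the end of a list. As a stand-in the −log10 q of interval 100000 was recorded and compared between libraries, as a sign of the strength of a list and not of accessibility: it was 2.32 to 18.7 in rat, 2.42 and 3.66 in mouse, 9.84 and 2.54 in the livers of macaque 1 and macaque 2, and 1.67 and 2.36 in their muscles.

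Entries with the same interval were kept once, with the best −log10 p. This left 209272 to 288652 unique intervals per macaque library, 182546 to 285075 per rat library and 233822 and 244439 in mouse. Intervals off the assembled chromosomes, at most 1.06% of a library (muscle of macaque 1), were left out. The strongest 100000 intervals by −log10 p, with ties ordered by fold ratio, formed lists of equal length. A library can gain intervals in an equal-length list only where it loses others, so all values are relative within a list. The median width of these intervals was 570 to 724 bp in the 8 matched brain regions of macaque 1 and 301 to 514 bp in those of macaque 2.

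Similarity of 2 libraries was the Jaccard index, the bases covered by both lists over those covered by either. Consensus regions were the merged deposited reproducible sets of a species, 263685 in macaque and 147074 in rat, so regions open only in muscle or dorsal S1 cannot be among them. In the 9 macaque sets of tissues from both animals, 5.34 to 26.0% of the intervals were identical to ones in the macaque 1 list and 0.008 to 0.724% to ones in the macaque 2 list, so the consensus is not independent of the lists of macaque 1. A region counted as present where an interval overlapped it by at least 1 bp. Presence in 5 cortical areas against 3 striatal regions was tested per region by an exact conditional test with the animal as stratum and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Similarities were tested by exact permutation of tissue labels, or by 100000 permutations for 10 tissues. Shares of regions carry 95% Wilson intervals.

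The genome was divided into windows of 100 kb, and the number of interval midpoints per window was analysed as log2(number + 1) in limma 3.58.1 (R 4.3.3) with moderated spread, in windows with a mean of at least 1 interval per library. Genes with flanks of 20 kb had been planned and windows set as the substitute; since no annotation of these builds was used here, windows took their place, and the 15 gene lists fixed beforehand, the share of peaks near transcription start sites and their alternatives were not run. The macaque model had a coefficient per tissue and the animal as a block over the 20 libraries of the 10 tissues sampled in both animals, and the rat model a coefficient per tissue over 8 libraries. The pairing in macaque comes from the labels, which give the same 2 animals for these tissues. Deviations of libraries of 1 animal from their tissue means had a median correlation of 0.044 (−0.114 to 0.693 over 90 pairs, mirrored by construction with 2 animals). This median hides a structure by class. Pairs of cortical areas had 0.554 to 0.693, and caudate or putamen with a cortical area −0.114 to 0.0125. A block common to all tissues cannot remove this, so limma p-values between striatum and cortex may be too small. In rat the animal can only be read from strain and sex, and correlations within such an animal were −0.014 to 0.058, so the block was an alternative there.

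Named windows were the 10 with the largest rise and the 10 with the largest fall among those past the threshold that moved the same way in both animals (in rat, whose groups did not overlap). Named regions were the 3 fully separated ones per direction with the best mean rank. Groups, tests, the naming rule and most alternatives were fixed before the data were examined. These alternatives were lists of 50000 or 150000 intervals, all intervals with a −log10 q of at least 2, windows of 250 or 50 kb, a pseudocount of 0.5, no filter, quantile normalization, another overlap, the block, and leaving out each library in turn. Leaving out the accumbens libraries of both animals or chromosomes 10, 16 and 19, keeping intervals off the assembled chromosomes, and fitting the cortical libraries alone were chosen after seeing the data, as were the placement of single libraries on cortex-only and striatum-only regions, the counts of regions restricted to a tissue and the shares per chromosome.

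Both kinds of test were tested on simulated data with known changes. The exact test on 263685 regions recovered 71.6% of strong and 2.32% of moderate differences with 0 false calls of 1849. The window model recovered 68% of 4-fold changes between cortex and striatum and 10% between liver and brain, but at most 1% for muscle, for accumbens and for both rat contrasts, each among 200 changed windows of 19225 to 21354. In the simulation of liver 2 of 12 calls were false, and in that of motor against auditory areas 1 of 12. The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.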

Results

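Accessible chromatin was profiled by bulk ATAC-seq, in which a transposase cuts open DNA, in 33 libraries from 3 species. The 23 macaque libraries came from 2 animals, a female of 12 years (macaque 1, 10 tissues) and a male of 4 years (macaque 2, 13 tissues). Both animals gave 5 cortical areas, namely the secondary auditory cortex (2A), the premotor area 6V, the supplementary motor area (SMA) and the dorsal and ventral primary motor cortex. Both also gave 3 striatal regions (caudate, putamen and nucleus accumbens), liver and muscle, while the dorsal and ventral primary somatosensory cortex (S1) and the cerebellum came from macaque 2 alone. The 8 rat libraries covered primary motor cortex (n = 3), striatum (n = 2) and liver (n = 3). Motor cortex and liver came from Sprague Dawley males at 86 days and Brown Norway males and females at 84 days. Striatum came from Brown Norway rats alone, a male and a female at 84 days. The 2 mouse livers came from a female and a male of 72 days. The title of the series names gene regulation behind fine motor control in primates and its evolution, and the design allowed motor areas to be compared with other areas and tissues.

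The depth in reads is unknown, because the files are peak lists. Per library they held 250785 to 297586 peak entries in macaque, 299063 to 300000 in rat and 265090 to 299707 in mouse. All comparisons used the strongest 100000 unique intervals of each library. The −log10 q of the last of these was 31.98 to 75.7 in the 8 matched brain regions of macaque 1 and 3.34 to 21.4 in those of macaque 2, so lists of macaque 2 reached weaker intervals. Animal, sex and age are the same split in macaque, and p-values there measure the spread between dissections of 2 animals. Gene names were not assigned, since no annotation of the builds in use (Mmul_8.0.1, rn6 and mm10) was used here, and positions are given instead.

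The deposited sets of reproducible peaks differed in size between tissues. In macaque the sets of the 5 cortical areas and 3 striatal regions had between 100043 (area 6V) and 122744 (area 2A) regions on the assembled chromosomes, against 69573 in liver. The sets of the cerebellum (59142) and ventral S1 (59790), each for a tissue with 1 library, held fewer regions than that of liver. Rat primary motor cortex had 102036 regions, rat striatum 68502 and rat liver 52745, and mouse liver had 53946. These are single sets with no replicates, so no test was made of their differences.

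Cortical and striatal chromatin formed separate classes in both macaques. In macaque 1, 2 cortical areas shared a mean Jaccard index of 0.720 ± 0.035 of their covered bases (SD, n = 10 pairs), 2 striatal regions 0.482 ± 0.208 (n = 3 pairs), and a cortical area and a striatal region 0.446 ± 0.103 (n = 15 pairs). In macaque 2 the values were 0.428 ± 0.021, 0.552 ± 0.088 and 0.230 ± 0.017. Caudate and putamen were alike within an animal (0.722 and 0.652) and between the animals, where the caudate lists shared 0.611 and the putamen lists 0.622. Pairs within a class exceeded pairs between classes by 0.218 in macaque 1 and 0.227 in macaque 2, each with a two-sided exact permutation p of 0.0179 over 56 splits, the smallest this design allows. Without the library labelled accumbens of macaque 1 the difference in that animal was 0.343. The library labelled accumbens of macaque 1 shared 0.585 with the cortical areas of its own animal and 0.361 with caudate and putamen, and its closest library was area 2A (0.608).

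**Figure D1:**
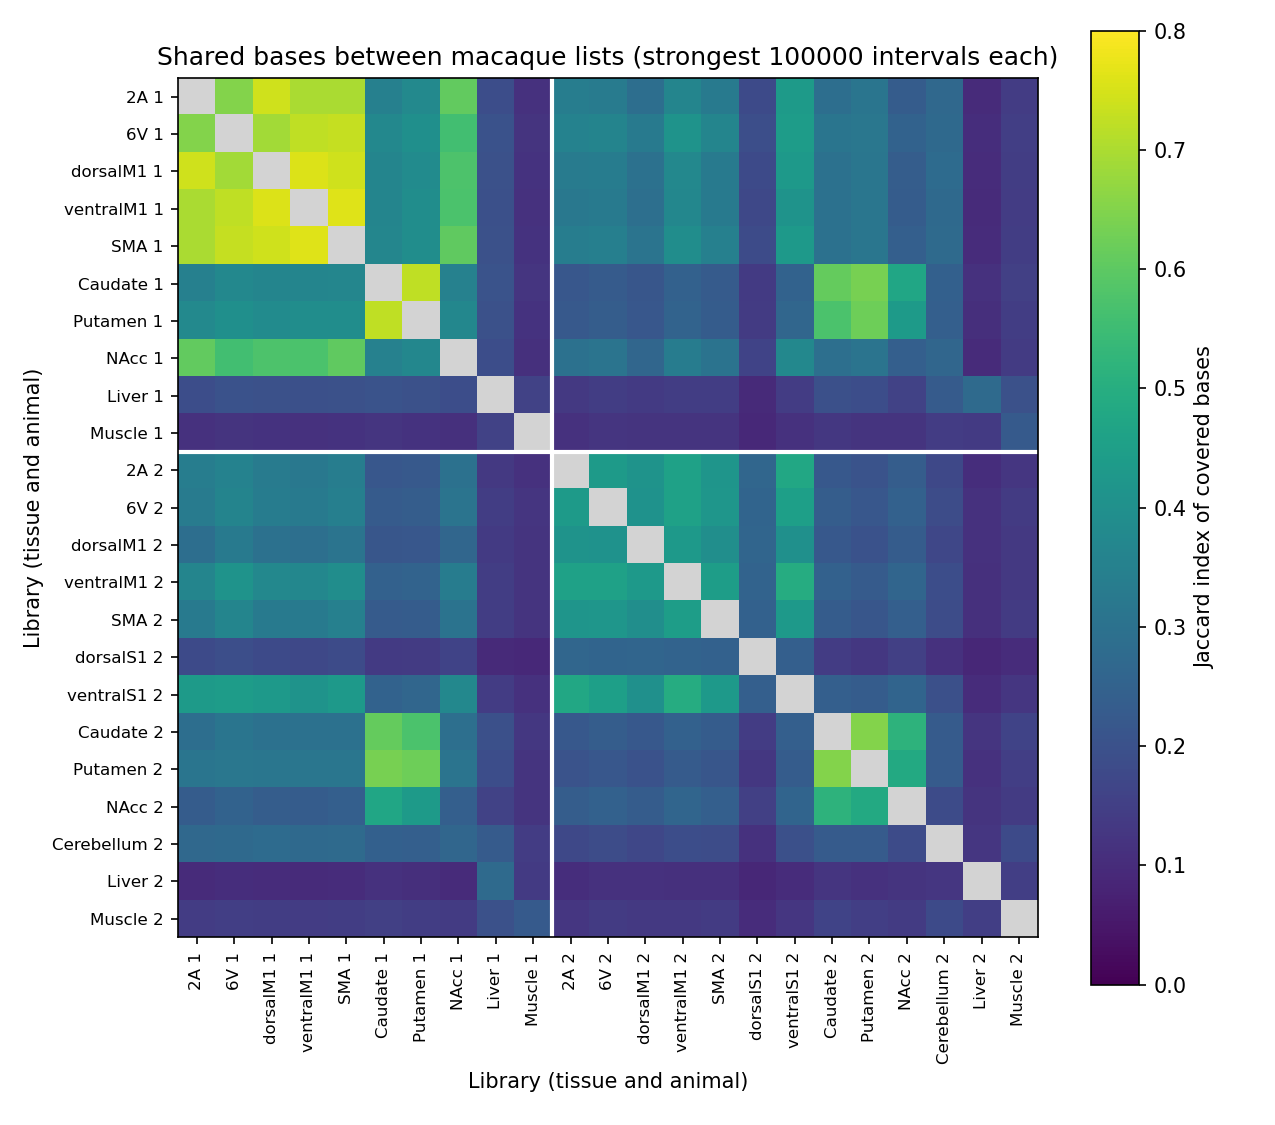
Jaccard index of covered bases for each pair of the 23 macaque libraries (colour scale, 0 to 0.8; grey on the diagonal), labelled by tissue and animal, with white lines between the animals. Caudate and putamen of the 2 animals share 0.611 and 0.622 with their own region in the other animal, and the library labelled NAcc of macaque 1 groups with the cortical areas of that animal.

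Many single regions were open in 1 of the 2 brain classes. Of 263685 consensus regions, 16199 were present more often in striatum and 11519 more often in cortex (exact test stratified by animal, Benjamini-Hochberg adjusted p under 0.05). In both animals 631 regions were present in all striatal libraries and no cortical one, and 1834 in all cortical libraries and no striatal one. Lists that were independent between the animals over all 263685 regions would share 150.6 and 302.1 such regions. This is a low benchmark, since 64225 regions were present in none of the libraries of the 8 matched brain regions. The library labelled accumbens of macaque 1 weighed heavily on the counts of called and separated regions. Without it, 25339 regions were called for striatum and 16472 for cortex, and 15442 and 9937 were fully separated. All 16199 and 11519 regions were among them. A further 22803 regions, 8.65% of all, were present in all 16 libraries of the 8 matched brain regions.

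Regions found in all 6 striatal and none of the 10 cortical libraries included, by best mean rank, chromosome 3 from 105921218 to 105922000, chromosome 1 from 117764224 to 117765263 and chromosome 6 from 116811672 to 116812314. Those found in all 10 cortical and none of the 6 striatal libraries included chromosome 12 from 43365436 to 43366385, chromosome 5 from 75094268 to 75094887 and chromosome 14 from 61880442 to 61881172. Each had an adjusted p of 0.0182 by the exact test. Without the library labelled accumbens of macaque 1, striatum-only regions with far better ranks led, such as chromosome 5 from 55281493 to 55282111 (mean rank 716 of the strongest 100000) and chromosome 18 from 19368539 to 19369209 (mean rank 731). The best cortex-only regions were then chromosome 4 from 134313829 to 134314506 (mean rank 1917) and chromosome 5 from 170175580 to 170176429 (mean rank 2676), each with an adjusted p of 0.00883 by the exact test.

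Single libraries were placed on sets of regions defined without the library itself and, in every case, without the library labelled accumbens of macaque 1. Caudate and putamen held 91.6 to 97.3% of the striatum-only and 0.471 to 8.5% of the cortex-only regions so defined, and the accumbens of macaque 2 held 79.3% and 6.46%. The 10 libraries of cortical areas held 0.361 to 2.94% of the striatum-only and 90.6 to 99.2% of the cortex-only regions. The library labelled accumbens of macaque 1 held 4.09% of the 15442 striatum-only regions (95% Wilson interval 3.79 to 4.41%) and 81.5% of the 9937 cortex-only regions (80.8 to 82.3%). These intervals cover counting error only. The deposited reproducible set named for the accumbens held 6.53% and 86.0% of these regions, whereas the caudate set held 99.7% and 2.51%. Of the intervals in the accumbens set 20.9% were identical to ones in the macaque 1 list and 0.0135% to ones in the macaque 2 list, so the set is not independent of that library. All 9 macaque sets of tissues from both animals showed this (5.34 to 26.0% against 0.008 to 0.724%).

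**Figure D2:**
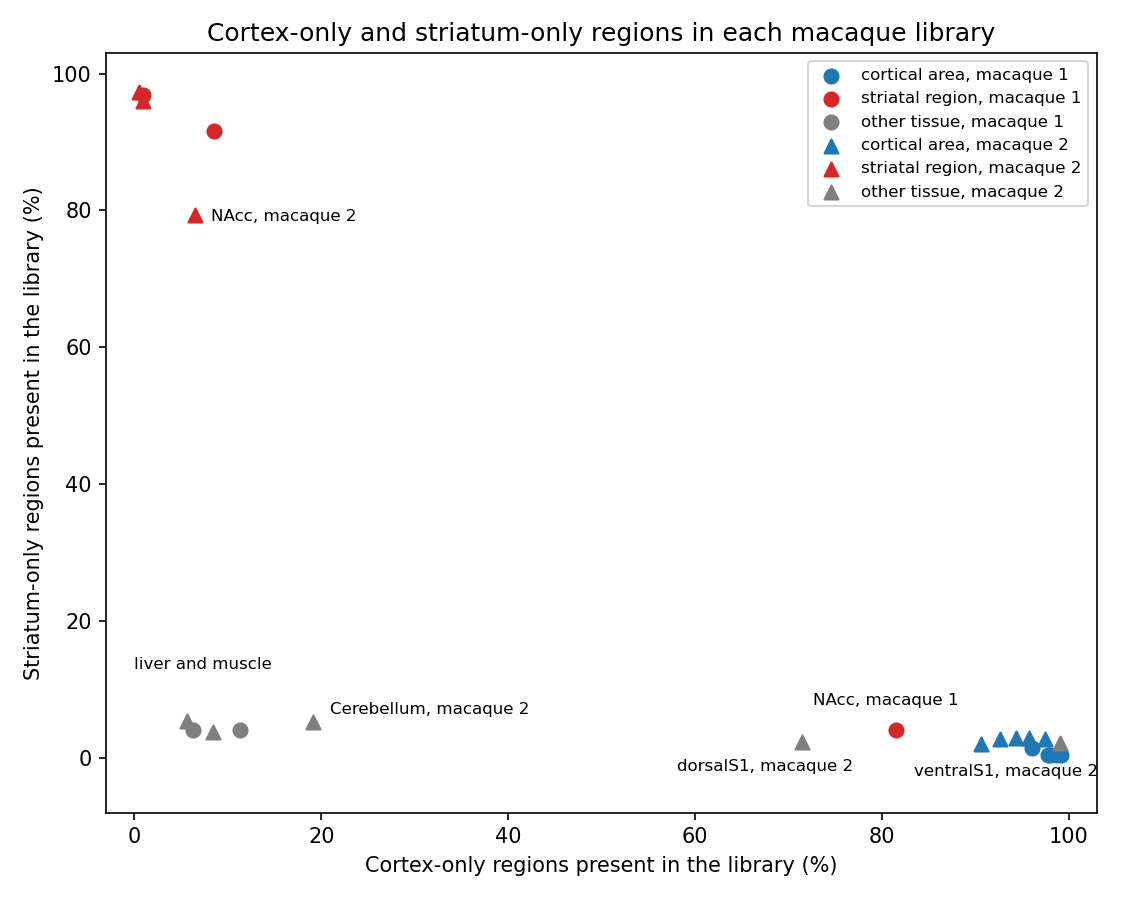
Share of cortex-only regions (x axis, %) and of striatum-only regions (y axis, %) present in each macaque library, one point per library, coloured by class and shaped by animal. Libraries of the 5 cortical areas sampled in both animals (blue) lie at 90.6% or more on the x axis, dorsal S1, drawn as other tissue, at 71.5%, caudate and putamen at 91.6% or more on the y axis, and the library labelled NAcc of macaque 1 at 81.5% and 4.09%.

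The same contrast was seen over 100-kb windows of the genome. In the limma model, 2531 of 26263 windows held more intervals in striatum and 3711 more in cortex, and 6218 of these 6242 windows moved the same way in both animals. The call averages both animals, so this agreement follows largely from the selection. Cortical areas of 1 animal deviated together from their tissue means, so the p-values of this contrast may be too small. The largest rise in striatum lay on chromosome 2 from 78600001 to 78700000, with 6.33 ± 3.20 intervals in striatum (SD, n = 6) and 0.6 ± 0.97 in cortex (n = 10), a log2 change of 2.08 (SE 0.37, limma adjusted p = 0.00164). It was followed by chromosome 6 from 72800001 to 72900000 (5.33 ± 2.88 against 0.5 ± 0.71) and chromosome 20 from 61700001 to 61800000 (5.5 ± 2.26 against 0.7 ± 1.06). The largest excess in cortex lay on chromosome 14 from 14600001 to 14700000, with 8.70 ± 1.42 intervals in cortex and 0.833 ± 2.04 in striatum (log2 change −2.83, SE 0.35, limma adjusted p = 0.000223). Next were chromosome 6 from 34400001 to 34500000 (7.40 ± 1.43 against 1.00 ± 2.45) and chromosome 18 from 43100001 to 43200000 (6.90 ± 1.37 against 0.5 ± 0.84). Over the 20 named windows the log2 changes, on the scale of log2(intervals + 1), ran from 1.92 to 2.08 and from −2.83 to −2.26.

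At the window on chromosome 14 all striatal libraries but the one labelled accumbens of macaque 1 had 0 intervals, and that one had 5. Without it, the excess there had a log2 change of −3.32 (SE 0.26), the rise on chromosome 2 became 2.46 (SE 0.35, 7.60 ± 0.894 intervals, n = 5), and 4 of the 10 windows with the largest rise in striatum lay on X. The counts were then 2524 and 3717, of which 5318 windows were among the 6242. Leaving out the accumbens, caudate or putamen of macaque 2 lowered the total to 3381, 3736 and 3497.

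**Figure D3:**
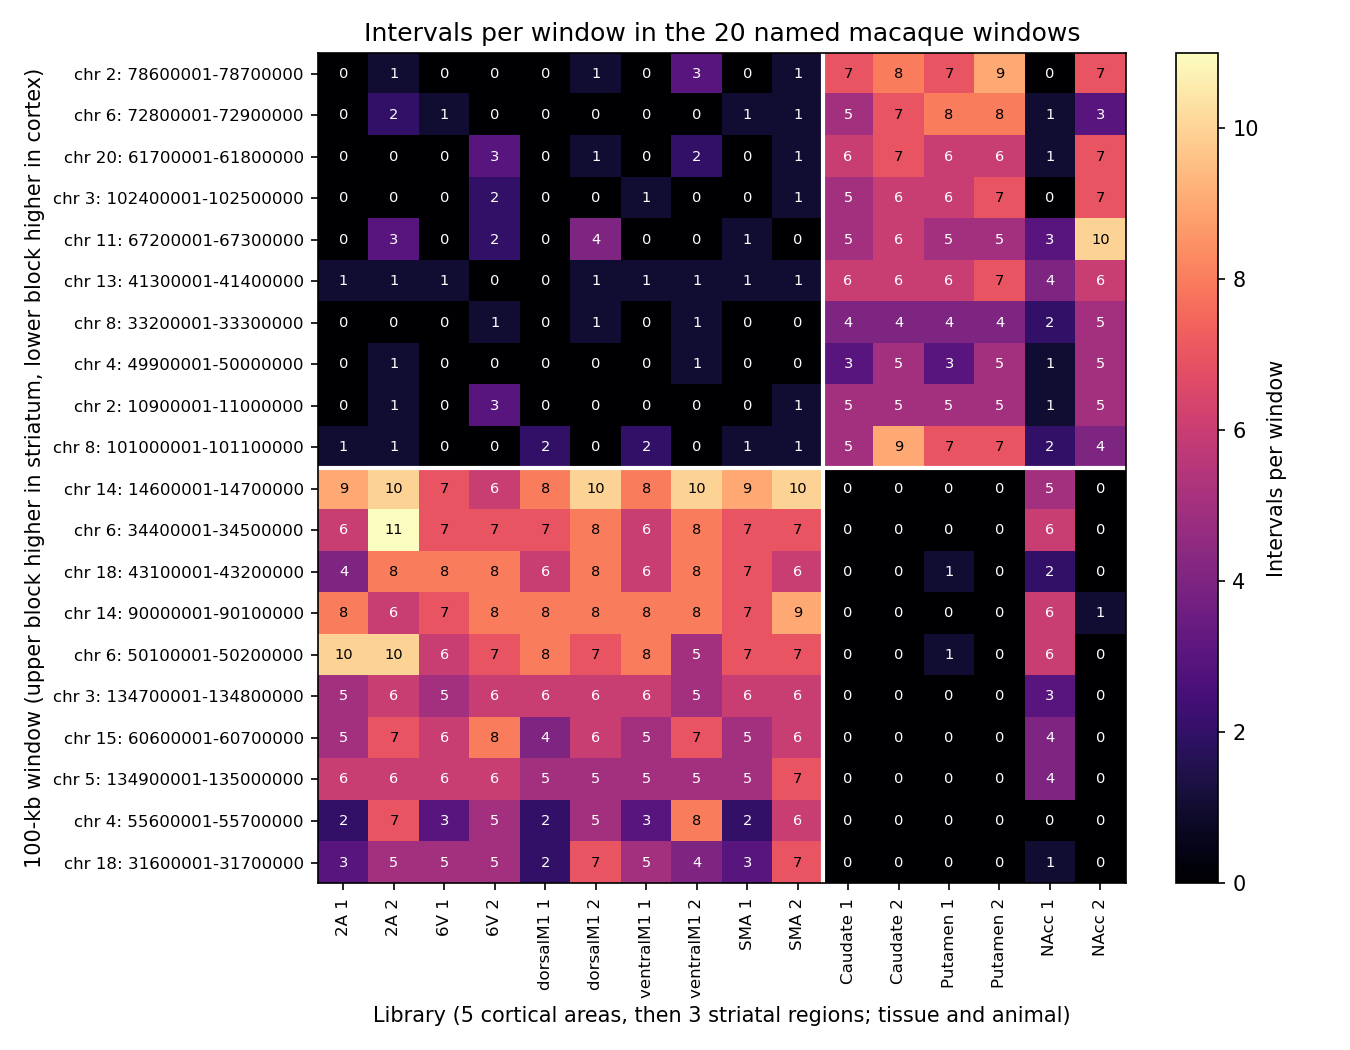
Number of intervals (colour and printed number) in the 20 windows of 100 kb with the largest changes between striatum and cortex, for each of the 16 brain libraries. The white lines part the 10 windows higher in striatum (upper block) from the 10 higher in cortex, and cortical from striatal libraries; the library labelled NAcc of macaque 1 has 5 intervals at the chromosome 14 window from 14600001 where the other striatal libraries have 0.

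Chromosomes differed in how these windows fell. On chromosomes 10, 16 and 19, 394 windows were higher in striatum and 28 in cortex, against 2137 and 3683 on the other chromosomes. These 3 chromosomes carried 7.45 to 8.79% of the list in the cortical areas of macaque 1 but 3.08 to 4.15% in those of macaque 2, where the accumbens had 4.54%, the caudate 9.07% and the putamen 9.87%. Cortex-only regions, judged within 1 animal, made up 4.81% of the regions on them in macaque 1 (against caudate and putamen only) and 0.333% in macaque 2 (against all 3 striatal regions), and 9.19% and 5.92% of those on the other chromosomes. Without these chromosomes 2208 windows were higher in striatum and 3763 in cortex.

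**Figure D4:**
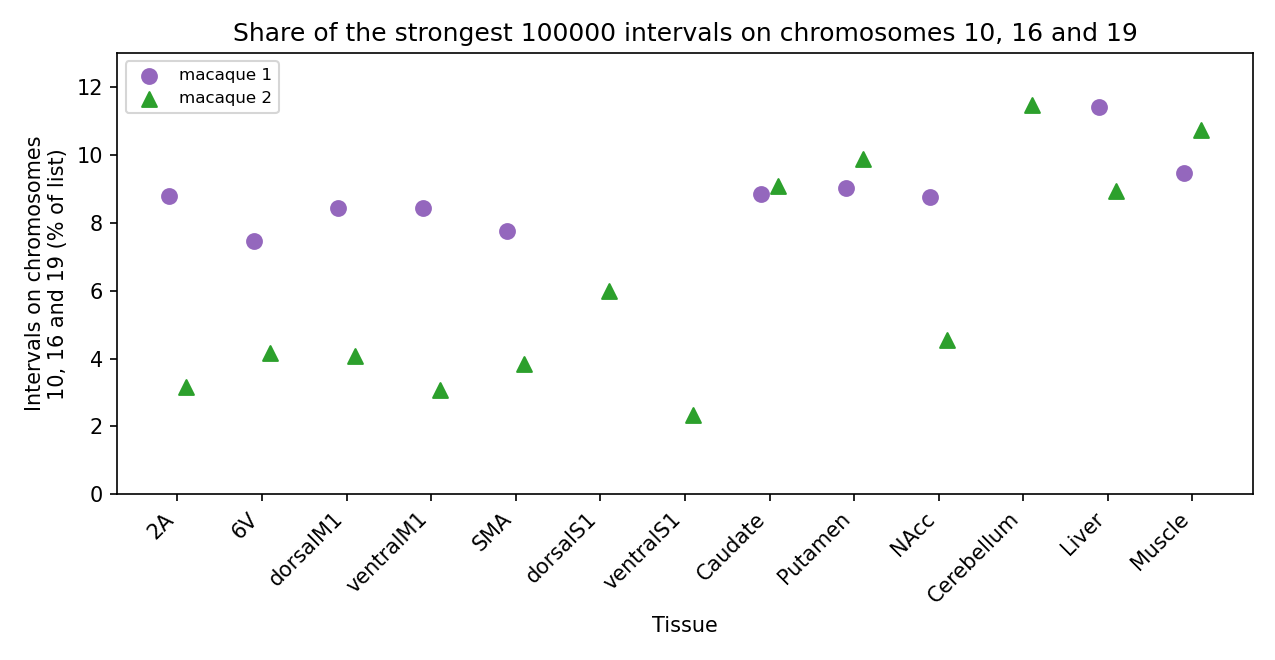
Share of each macaque list of the strongest 100000 intervals that lies on chromosomes 10, 16 and 19 (y axis, %), by tissue (x axis) and animal, one point per library. The 5 cortical areas have 7.45 to 8.79% in macaque 1 and 3.08 to 4.15% in macaque 2.

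The comparison of accumbens with caudate and putamen, the ventral and the dorsal striatum, had 1 library per animal on the accumbens side, and the one of macaque 1 held cortex-only rather than striatum-only regions (81.5% and 4.09%). It gave 25 windows higher and 8 lower in accumbens (limma). The largest rise was on chromosome 18 from 49100001 to 49200000, with 5.5 ± 2.12 intervals in accumbens (SD, n = 2) and 0.25 ± 0.5 in caudate and putamen (n = 4), a log2 change of 2.41 (SE 0.36, limma adjusted p = 0.0163). The largest fall was on chromosome 20 from 3100001 to 3200000, with 0 intervals in both accumbens libraries and 4.00 ± 0.816 in caudate and putamen (log2 change −2.31, SE 0.33). These calls rested on single libraries: limma called 0 without the library labelled accumbens of macaque 1 (1975 windows at an unadjusted p under 0.05) and 0 without the putamen of macaque 2 (2199), 2 were left without the caudate of macaque 2, 15 without the putamen of macaque 1 and 18 without the caudate of macaque 1. There were 257 without the accumbens of macaque 2.

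Between cortical areas no window was called. For motor areas (dorsal and ventral primary motor cortex, area 6V and SMA) against area 2A, limma called 0 of 26263 windows, with 608 at an unadjusted p under 0.05. For dorsal against ventral primary motor cortex it called 0, with 282 at an unadjusted p under 0.05. Both counts lie below the share of 0.05 of the windows that would pass with no difference at all. The model was thus cautious for these contrasts, and 0 calls do not show that the areas are alike. In data simulated for these contrasts the model recovered 11% and 0% of windows with a 4-fold change. The same simulation recovered 0% for muscle, where windows were called in the real lists, so it sets no limit on what these libraries can show. With the 10 cortical libraries alone in the fit, limma again called 0 in both, with 1631 and 826 windows at an unadjusted p under 0.05. In macaque 1, of the 5 areas, the ventral primary motor cortex and the SMA shared the most bases (0.761), and the dorsal and ventral primary motor cortex shared 0.759. In macaque 2, among the 5 areas sampled in both animals, area 2A and the ventral primary motor cortex shared the most (0.457), and the dorsal and ventral primary motor cortex shared 0.434.

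Within cortex, the same area in the 2 animals was not measurably more alike than different areas. The same cortical area in 2 animals shared 0.343 of its bases and different areas shared 0.340, a difference of 0.00347 (one-sided exact permutation p = 0.133, smallest possible 0.0083). Over the 8 brain regions the same region exceeded different regions by 0.0849 (exact permutation p = 0.000397), and over all 10 tissues by 0.124 (permutation p = 1e-05, the smallest that 100000 permutations can give). These permutations also exchange labels between cortex, striatum and other tissues, so both differences include that between tissue classes. In each animal 2 of the 8 brain libraries were closest to their own region in the other animal. Over the 10 tissues 4 libraries of each animal were. For the 3 striatal regions the difference was 0.0385, and its exact permutation p of 0.167 is the smallest this design allows.

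Liver and muscle differed from brain at many windows. Within each animal their lists were weaker than those of the 8 matched brain regions. The −log10 q of interval 100000 was 9.84 and 2.54 in the livers of macaque 1 and macaque 2. It was 1.67 and 2.36 in the muscles of these animals, and 31.98 to 75.7 and 3.34 to 21.4 in their brain regions. The effect of this on the counts of windows was not tested. Liver was higher at 3009 and lower at 4938 windows than the mean of 8 brain regions, and muscle was higher at 2059 and lower at 3204 (limma). The largest rise in liver was on chromosome 3 from 125100001 to 125200000, with 14.5 ± 6.36 intervals in liver (SD, n = 2) and 0.375 ± 0.885 in brain (n = 16; log2 change 3.60, SE 0.45, limma adjusted p = 0.000114). Adjacent windows were named on chromosome 10 from 55600001 to 55800000 and on chromosome 19 from 36600001 to 36800000, where both livers together averaged 8.5 to 10 intervals per window. Chromosomes 10, 16 and 19 held 11.4 and 8.94% of the liver lists of macaque 1 and macaque 2. They held only 3.08 to 4.15% of the lists of the cortical areas of macaque 2. Liver was not recounted without these chromosomes. On chromosome 18 from 39700001 to 39800000 both livers had 0 intervals and brain 10.6 ± 2.70 (log2 change −3.50, SE 0.28). Without the liver of macaque 1, 906 windows were higher and 2194 lower (3100 in all), and without that of macaque 2, 1681 and 4405.

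In muscle the largest rise was on chromosome 6 from 139100001 to 139200000, with 9 ± 1.41 intervals and 0 in all 16 brain libraries (log2 change 3.31, SE 0.19, limma adjusted p = 1.11e-06). Next came chromosome 10 from 69400001 to 69500000 (13 ± 2.83 against 1.19 ± 1.22). Chromosomes 10, 16 and 19 held 9.47 and 10.7% of the muscle lists of macaque 1 and macaque 2, and muscle was not recounted without them either. In the muscle of macaque 1 only 84658 intervals had a −log10 q of at least 2, fewer than the 100000 used. That library held intervals on 1600 named sequences, against 22 in the muscle of macaque 2. Whether it was processed differently is unknown. The windows on X from 139500001 to 139600000 and on chromosome 7 from 90500001 to 90600000 were empty in both livers and both muscles, while brain held 7.38 ± 1.78 and 7.13 ± 1.02 intervals there. Without the muscle of macaque 2, 864 windows were higher and 1910 lower (2774 in all), and without that of macaque 1, 1314 and 2954.

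Of the 44235 consensus regions present in both macaque livers, 17695 (40.0%) were present in none of the 16 libraries of the 8 matched brain regions. Muscle had 2462 such regions among 25215 (9.76%), a share held low by construction, since no muscle set entered the consensus, and not comparable with that of liver. Of the 22803 regions open in all of these 16 libraries, which leave out S1 and the cerebellum, 9729 (42.7%) were also open in both livers and both muscles, and 7033 (30.8%) were absent from both livers.

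**Figure D5:**
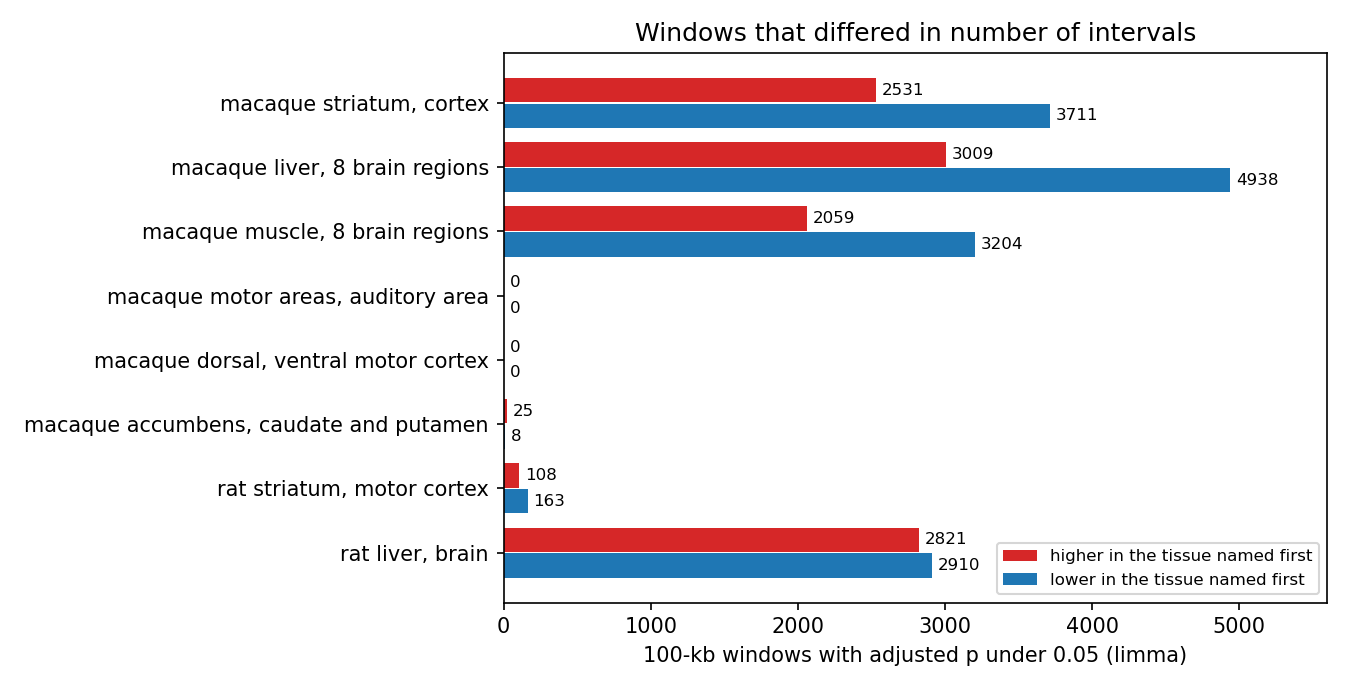
Number of 100-kb windows with a limma adjusted p under 0.05 (x axis) for each of the 8 comparisons, with red bars for windows higher and blue bars for windows lower in the tissue named first. The bars range from 0 in the 2 comparisons within cortex to 4938 for windows lower in macaque liver.

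The somatosensory and cerebellar libraries came from 1 animal and have no replicate check. Ventral S1 was closest to the ventral primary motor cortex of the same animal (0.497) and held 99.0% of the cortex-only and 2.18% of the striatum-only regions. Dorsal S1 was closest to area 2A (0.265) and held 71.5% and 2.37%. The cerebellum shared 0.180 with the cortical areas and 0.215 with the striatal regions of its animal, but 0.274 and 0.251 with those of macaque 1, where its closest library was the dorsal primary motor cortex (0.279). It held 19.1% and 5.18%.

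Rat tissues were separated as well. All 3 motor cortex lists held intervals on 128 to 138 named sequences and both striatal lists on 21 and 22, so any difference in processing behind this coincides with the tissue. The 3 primary motor cortex libraries shared 0.599 ± 0.023 of their bases (SD, n = 3 pairs), the 2 striatal libraries 0.520, and the 3 livers 0.297 ± 0.076 (n = 3 pairs). Motor cortex and striatum shared 0.341 ± 0.048 (n = 6 pairs), and liver shared 0.149 ± 0.012 with motor cortex and 0.163 ± 0.009 with striatum. Pairs within a tissue averaged 0.458 and pairs between tissues 0.208, with an exact permutation p of 0.00357, the smallest of 280 splits. Of regions found in all libraries of a tissue, 16571 (22.1%) in motor cortex, 13184 (19%) in striatum and 9666 (28.0%) in liver were found in no library of the other tissues.

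Rat striatum had more intervals than motor cortex at 108 of 23778 windows and fewer at 163 (limma). Both striatal libraries were Brown Norway while motor cortex included a Sprague Dawley library, so strain was not balanced. The largest rise was on chromosome 2 from 82200001 to 82300000, with 7.5 ± 0.707 intervals in striatum (SD, n = 2) and 0 in all 3 motor cortex libraries (log2 change 3.08, SE 0.47, limma adjusted p = 0.0385). The largest excess in motor cortex was on chromosome 7 from 36800001 to 36900000, with 7.33 ± 0.577 intervals and 0 in both striatal libraries (log2 change −3.06, SE 0.24, limma adjusted p = 0.00891). No call was left with the animal, read from strain and sex, as a block (3846 windows at an unadjusted p under 0.05 in limma), and leaving out any 1 of the 5 brain libraries left at most 7.

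Rat liver was higher than brain at 2821 and lower at 2910 windows (limma). On chromosome 6 from 143000001 to 143100000 the livers held 10 ± 1.73 intervals (SD, n = 3) and all 5 brain libraries 0 (log2 change 3.45, SE 0.15, limma adjusted p = 0.000499). On chromosome 1 from 134500001 to 134600000 brain held 11.2 ± 1.92 intervals and liver 0.333 ± 0.577 (log2 change −3.23, SE 0.26). The total fell to 3264 without the striatum of the Brown Norway male, 3540 without that of the female, 3558 without motor cortex of the Brown Norway male and 3725 without that of the female.

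In the 2 mouse livers, 65.3% of the strongest 100000 intervals of the female overlapped one of the male, with a Jaccard index of 0.454 over covered bases. With 1 library per sex no test was made. Across the 10 macaque tissues the X chromosome carried 3.017 ± 0.133% of the intervals in the female and 2.998 ± 0.857% in the male, a difference of 0.0191 points (two-sided exact permutation p = 0.943, n = 10 pairs). Its sign and size depended on the processing, from −0.439 to 0.563 points over the alternatives. Over the 8 brain regions alone the means were 3.022% in the female and 3.368% in the male, with 2 of 8 regions higher in the female (difference −0.346 points, exact permutation p = 0.109). Y chromosome intervals numbered 44 to 199 in each of the 13 lists of the male macaque and 0 in 9 of the 10 lists of the female, whose muscle list had 4.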

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

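Of the tests below, those of a wrong label, of a swap, of cortical tissue, of weak lists, of a shared bias and of the library labelled accumbens as the cause of the difference between animals, and the splits of the samples for regions, striatal windows and rat liver, were chosen after the result was seen. Outlying libraries were sought in 28 combinations of a group and a measure, of which chance alone would mark about 1 in 20, and 4 were marked.

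The library labelled accumbens of macaque 1 lay apart from the other 5 striatal libraries: its mean similarity to striatum minus that to cortex was −0.131, against 0.190 in the nearest other striatal library. It held 4.09% of the striatum-only regions, about as much as the liver (4.08%) and muscle (4.14%) of the same animal, and 81.5% of the cortex-only ones. The 10 libraries of cortical areas held 0.361 to 2.94% and 90.6 to 99.2%, so it lay near them but outside their range. A wrong label, or tissue taken largely from cortex, may account for this. A swap with a library of macaque 2 is argued against by 0 intervals on the Y chromosome, where all lists of that male have at least 44. A dissection that mixed some striatum into cortex was neither shown nor excluded. Of the 1544 strongest striatum-only regions its whole list held 20.5% (95% interval 18.5 to 22.6%), above the 16.5% (14.7 to 18.4%) of area 2A in that animal. It was within the interval of ventral primary motor cortex of macaque 2 (18.98%, 17.1 to 21.01%), whose whole list is longer (269422 against 217870 intervals). Of all striatum-only regions it held 20.4%, against 17.7% in area 2A of that animal. The cortical libraries helped to define these regions and this library did not. No biological explanation was tested, and the accumbens of macaque 2, with 79.3%, was striatal by the same measure.

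The accumbens of macaque 2 was outlying among striatal libraries in another measure, with 4.54% of its list on chromosomes 10, 16 and 19 against at least 8.77% in the other 5. Cortical tissue as such does not carry the low share, since the lowest value among the cortical areas of macaque 1 was 7.45% and the highest in macaque 2 was 4.15%. The liver of macaque 2, whose list ends at a lower −log10 q (2.54) than those of its cortical areas, has 8.94% on these chromosomes. The liver of macaque 1, with a stronger list (9.84), has 11.4%. The liver share was thus also lower in the weaker list, so this comparison cannot decide on weak lists. In macaque 2, muscle (2.36) and cerebellum (5.54) had 10.7 and 11.5%. The accumbens (9.53) and ventral S1 (7.95), with stronger lists, had 4.54 and 2.33%. Caudate (13.9) and putamen (21.4), with the strongest lists, had 9.07 and 9.87%. List strength alone thus did not order the shares, though tissue differs in these comparisons. Over the 17 other autosomes, the log ratio of accumbens to caudate and putamen in macaque 2 followed that of cortex in macaque 2 to cortex in macaque 1 (Pearson r = 0.957 across chromosomes, which are not independent replicates), so a bias shared by these libraries, such as one tied to base composition or to a library batch, may account for the pattern. Base composition was not tested, since no genome of this build was used here, and the age and sex of macaque 2 stay open.

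The difference between striatum and cortex was itself different in the 2 macaques at 820 of 25755 windows (limma interaction term). The signed value of striatum minus cortex was higher in macaque 2 at 422 of them and lower at 398. These signs do not tell in which animal the classes lay further apart. Among the 56 ways to divide the 8 regions, 1 gave as many calls, the real one, and the highest of the others gave 51. Every other division mixes cortex with striatum in at least 1 group, so the difference between the classes adds to its spread. The comparison of divisions therefore cannot decide on chance. The library labelled accumbens of macaque 1 is not needed for such calls, since a fit without it gave 503 and one without both accumbens libraries 3363. How many of these windows are among the 820 was not counted. Chromosomes 10, 16 and 19 held 14.6% of the calls against 7.62% of the windows tested, too few for them to be the main source. A bias over all chromosomes, the depth of the lists, sex and age may each contribute and cannot be separated in 2 animals.

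For mean similarity to striatum minus that to cortex, area 2A of macaque 1 had −0.133 against −0.144 in the next of the 5 cortical areas of its animal; its similarity to striatum (0.361) and to cortex (0.4934) were both the lowest of the 5, and the striatal mean includes the library labelled accumbens of that animal. The ventral primary motor cortex of macaque 2 had the highest −log10 q at interval 100000 among the cortical areas of its animal (4.74 against 3.58 in the next). In the list of the female mouse 6 intervals lay on the Y chromosome, and in that of the male 4. In the muscle list of the female macaque 4 intervals lay on Y, where the other 9 lists of that animal had 0.

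Other divisions of the samples were counted for the 3 remaining comparisons. For regions, the real division of the 8 macaque brain regions gave 27718 calls and was 1 of 56 with as many, and the highest of the others gave 0. For windows the real one gave 6242, again 1 of 56, and the highest other gave 2140, for dorsal primary motor cortex, caudate and putamen, which keeps 2 of 3 striatal regions together. For rat liver against brain, fitted as 2 groups, the real one gave 4755, 1 of 56, and the highest other gave 146. Every other division mixes cortex with striatum, or liver with brain, in at least 1 group, so the tissue difference is diluted there or counted as spread. For these 3 results the counts show that the real division gave the most calls. They cannot decide on chance.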

How the results depend on the processing

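Removing chromosomes 10, 16 and 19 or both accumbens libraries, keeping intervals off the assembled chromosomes and fitting the cortical areas alone were alternatives chosen after seeing the data. Of 151 alternatives other than leaving out a library or tissue, 106 kept direction, side of the threshold or count. With 1 library or tissue left out, 163 of 190 did. A count was taken as kept within a wide margin, such as 4518 windows without the block against 6242 for striatum against cortex. The 106 include a filter on each deposited set (−log10 q of at least 4), which changed the sets little. They also include all 10 alternatives of each comparison within cortex, where 0 windows stayed 0. The 106 thus say less about the other results. All alternatives kept the direction and side of the threshold of the similarity results within cortex and striatum, across animals for 10 tissues and 8 brain regions, and for rat tissues, though the difference in macaque 2 (0.227) was 0.148 with all intervals at a −log10 q of at least 2. With the Jaccard index of consensus regions the differences were larger, at 0.312 in macaque 2, 0.1905 for 10 tissues (0.1237), 0.1216 for 8 brain regions (0.0849) and 0.3797 in rat (0.2503). Both comparisons within cortex stayed at 0 windows in limma (44 to 1631 at an unadjusted p under 0.05 over the alternatives that kept all libraries of the contrast). Alternatives that need gene positions were not run, and with 3 striatal regions no tissue was left out. List depth is unknown in reads, and its effect on these counts was not tested.

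Calls of regions (27718; 16199 striatum, 11519 cortex) became 14933 (8273, 6660) with 50000 intervals, 47494 (27314, 20180) with 150000, 45773 (27967, 17806) with all intervals at a −log10 q of at least 2, 17694 (cortex 3563) with 0.5 of the region covered, and 43550 (25991, 17559) with no replicate block. Leaving out a library gave 28483 to 41811 (striatum 16479 to 25339, cortex 11942 to 16472), with 41811 only without the library labelled accumbens of macaque 1.

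With all intervals at a −log10 q of at least 2, windows called were 3352 for striatum against cortex, 4294 for liver, 8014 for muscle, 0 for accumbens (3125 at an unadjusted p under 0.05), 0 for rat striatum (2503) and 3098 for rat liver. With windows of 250 kb they were 2535, 3754, 2178, 1, 49 and 2850, and with 50 kb 9662, 12082, 8565, 71, 1087 and 9089, where the number of windows tested differs by construction. Accumbens windows (33) became 213 with 50000 intervals, 82 with 150000, 111 with a pseudocount of 0.5 and 64 with quantile normalization. Rat striatal windows (271) became 1208 with 50000 intervals, 0 with 150000 (3539 at an unadjusted p under 0.05), 498 with a pseudocount of 0.5, and 0 with the replicate block, which moved no other rat count by over 1.5 times. Macaque windows without the block were 4518, 6425, 3858 and 25 for striatum, liver, muscle and accumbens.

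Leaving out a library gave 3381 to 6241 windows for striatum against cortex, 3100 to 8017 for liver, 2774 to 5360 for muscle, 0 to 257 for accumbens, 0 to 7 for rat striatum and 3264 to 8239 for rat liver; a lone library was assumed to vary like the other tissues.

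The difference for the same cortical area across animals (0.00347) turned to −0.000117 without area 2A (range −0.000117 to 0.00566 with an area left out), and was 0.00185 with all intervals at a −log10 q of at least 2 and 0.00671 with consensus regions. The female minus male X share (0.0191) turned to −0.00478 without caudate, −0.0241 without putamen, −0.115 without liver, −0.171 without muscle (range −0.171 to 0.131) and −0.439 with 50000 intervals, and rose to 0.563 (exact p = 0.0430) with all intervals at a −log10 q of at least 2. The mouse overlap (65.3%) became 83.7% with 50000 intervals, 56% with 150000 and 57.6% with reciprocal overlap of 0.5. Except where stated, the cause was not tested.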

Other observations

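No explanation was tested in this part; the sets described here were chosen after seeing the data.

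The cerebellum of macaque 2 had more regions of its own than ventral S1 of the same animal. Of the 78435 consensus regions present in the cerebellum, 12663 (16.1%, 95% Wilson interval 15.9 to 16.4%) were present in none of the other 22 macaque libraries. Ventral S1 had 1082 such regions of 90852 (1.19%). Dorsal S1 had 407 of 52376 (0.777%), a count held low by construction, since no dorsal S1 set entered the consensus. The other 22 libraries of ventral S1 include many cortical ones, whereas those of the cerebellum include no second cerebellum. The higher count of the cerebellum thus follows in part from the design. All intervals of the cerebellum and ventral S1 sets (100% each) were also identical to ones in their own lists. Of the 24783 regions open in all 8 matched brain regions of macaque 2, ventral S1 held 98.5%, dorsal S1 79.5% and the cerebellum 72.1%. The list of dorsal S1 ended at a −log10 q of 2.32, that of the cerebellum at 5.54 and that of ventral S1 at 7.95, so the 3 lists are not equally strong.

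In rat, 19721 of 147074 consensus regions (13.4%) were present in all 8 libraries of motor cortex, striatum and liver, and 16256 of the 46005 regions in all 5 brain libraries (35.3%) were absent from the 3 livers. Of the 44235 regions in both macaque livers, 14275 (32.3%) were absent from the 16 libraries of the 8 matched brain regions and from both muscles; S1 and the cerebellum were not checked. Between the macaques, the caudate (0.611) and putamen (0.622) lists shared more bases with their own region than the livers (0.277) or muscles (0.227) did.

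In rat, motor cortex of the Sprague Dawley male had 4.93% of its list on chromosome 3, where the other 2 motor cortex libraries had 6.60% and 6.65%, and 5.29% on chromosome 9, where they had 4.71% and 4.67%. The liver of the same strain had 6.61% on chromosome 3. On chromosome 10 that liver had 4.76% of its list against 2.71% and 2.79% in the Brown Norway livers, and on X 1.43% against 2.67% and 3.29%. That liver list was also the only one of the 3 with intervals on unplaced sequences (171 named sequences against 22 and 21) and the weakest (−log10 q of 2.32 at interval 100000 against 3.96 and 2.68), so strain cannot be told apart from processing or list strength here.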
